A study of Mus musculus with 2 samples.

How the data were processed

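Single-cell RNA was measured in 2 libraries of CD45-positive cells from mouse lungs, 1 library per group, with the groups taken from the genotype labels. The libraries were made with the Chromium Single Cell 3' v3.0 kit per the labels' protocols, and Cell Ranger 6.1.2 and the mm10 genome build are named per the submitters' processing notes. The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, over 32285 genes. How barcodes were called as cells, the annotation used and the treatment of reads that match several genes or the opposite strand are not given in the sources used here. No barcode had fewer than 500 UMIs, so the tables were already filtered when deposited, and any cell type with less RNA than that is missing from the shares. A UMI marks 1 captured molecule, so intervals on UMI counts cover counting error and not the difference between animals. Reads of near-identical copies (Hspa1a and Hspa1b, class I heavy chains such as H2-Q7 and H2-T22, Ly6c2, Ftl1 and Fth1) can be split or lost in counting, and their values are uncertain.

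Cells with 200 or more detected genes and at most 10% mitochondrial UMIs were kept, 10379 of 10674 and 7631 of 7821. Doublets were called per library with Scrublet at its automatic threshold. It called 279 cells (3.66%) in the library labelled KL_Gpx4, which were removed, and 0 of 10379 in the library labelled KL, where its threshold of 0.626 lay above every score. The doublet step has therefore not worked in the library labelled KL, and doublets there remain. With the other library's threshold of 0.212 it would call 193 cells, which was run as an alternative. The retained cells numbered 10379 and 7352.

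Counts per cell were scaled to 10000, logged, and clustered together with scanpy 1.11.5 (2000 variable genes with the library as batch key, 30 principal components, 15 neighbours, Leiden resolution 1) with no integration of the libraries. Clusters were named from 20 fixed marker sets. A cluster took the class with the highest mean log2 fold of its markers (CPM plus 10, folds limited to 3 either way) if that mean was 0.5 or more and 3 or more markers were detected in 10% of its cells at a log2 fold of 1 or more. A cluster stayed unnamed if its 10 top genes held more markers of another class, or none of its own where its library's median UMI count was over 3 times its own. This scoring was set after the data were examined. The cluster it left unnamed held 22.5% and 0.422% of the retained cells. Regulatory T cells are a cluster of the T cell class named from its own markers. Apart from the level of Gpx4, which is given for classes of 50 or more cells and for epithelial cells, genes were not compared within alveolar macrophages, since the library labelled KL_Gpx4 held 53 of them. Shares are of all retained cells with exact Clopper-Pearson intervals.

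For each class with 100 or more cells in each library, UMIs were summed per gene and library and expressed as counts per 1000000 UMIs of the class (CPM). Levels have exact Poisson intervals, and the ratio of the library labelled KL_Gpx4 over the library labelled KL has an exact conditional interval, on the log2 scale or as a fold. A gene with 0 UMIs in a library was set at a floor of 3 counts there. With 1 library per group no p-value was computed. Gene lists were described by the median log2 ratio of members with 20 or more UMIs over both libraries, by how many members differed by 1.5-fold or more, and by the percentile of the median among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. In neutrophils and non-classical monocytes the median of all genes lay more than 0.1 from 0 (-0.36 and 0.14), and values said to be relative have it subtracted. Counts of members past 1.5-fold are without this subtraction, so they lean to lower in neutrophils and to higher in non-classical monocytes. Under an alternative the median of all genes under that alternative is subtracted.

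The cell filter, the clustering settings, the markers, 28 gene lists, the rule for naming genes and the alternatives listed below were fixed before the data were examined. The rule named, Gpx4 in every class and, per class, up to 5 genes with the highest and 5 with the lowest ratio, and members of the lists. Ranked genes needed 50 CPM where they were higher, detection in 10% of cells there, 100 UMIs over both libraries and 10% of the level in the top class, against free RNA, and sex-linked, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes were not ranked. List members needed 25 CPM and a 1.5-fold ratio, up to 6 per list and class. The limit against free RNA was not applied to them, and Ly6c2 in T cells (9.47% of the top class), Ccl24 in classical monocytes (6.48%) and C1qa, C1qc and Cxcl2 in cDC2 stood under it. The genes around Gpx4, the Lyz2 levels in T and B cells, Cd8a and Cd8b1, which of the gene lists the text gives per class and the split by Xist and Y-linked UMIs were chosen after values were seen. Gene positions are from the GENCODE M21 annotation of GRCm38.

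The alternatives fixed then were all barcodes, a stricter filter (500 genes and 5% mitochondrial UMIs), doublet calls kept, Leiden resolutions 0.5 and 2, separate clustering, classes per cell without clusters, a denominator without neutrophils, TMM scaling (edgeR 4.0.16 in R 4.3.3), median-of-ratios scaling, means of per-cell CPM, cells thinned to 1000 or 500 UMIs, and list members with 1 or 100 UMIs. All barcodes here means no filter on genes or mitochondrial UMIs, with doublet calls still removed. The ratio and list steps were tested on simulated data drawn from the measured means with 200 planted genes. Class sums were drawn as Poisson counts, as the intervals assume, with no spread between cells, doublets or free RNA. The simulation therefore checks the calculation and does not show how well the intervals hold for real cells. For T cells (13261 genes) the intervals held the true ratio for 98.5%, 98.5% and 96.8% of genes planted at 1.5-fold, 2-fold and 4-fold, and all had the right direction. For cDC2 (9662 genes) the shares were 92.4%, 95.4% and 90.6%, with the right direction for 93.9% at 1.5-fold and 100% above it. Of 200 unchanged random lists, 7 in T cells and 8 in cDC2 fell outside the central 95% of their random medians. Numerical work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.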

Results

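The study sorted CD45-positive cells, that is white blood cells, from tumour-bearing mouse lungs and profiled them by droplet single-cell RNA sequencing of transcript 3' ends. Lung tumours were started by intranasal adenovirus carrying Cre recombinase, which switches on an oncogenic Kras allele (Kras G12D) and removes both floxed copies of Lkb1, the kinase gene whose official symbol is Stk11. There were 2 groups with 1 library each. The library labelled KL came from mice with these alleles alone, and the library labelled KL_Gpx4 from mice that also carried a homozygous Gpx4 allele written m/m in the genotype label. Gpx4 encodes glutathione peroxidase 4, the enzyme that reduces lipid peroxides and holds off ferroptosis, an iron-dependent form of cell death. The series title places the loss of Gpx4 in tumour cells, so the comparison asks how the immune cells of the lung differ when the tumour cells lack this enzyme. Both libraries were taken 10 weeks after the virus. The treatment label names tamoxifen for the library labelled KL and not for the other, while the shared growth protocol names it for both. The series-level design text gives other alleles, Tp53 and IL8 in place of Lkb1, and the groups here follow the genotype labels of the samples.

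The library labelled KL held 10674 barcodes with 56996343 unique molecular identifiers (UMIs, each counting 1 captured transcript), and the library labelled KL_Gpx4 held 7821 barcodes with 42052107 UMIs. These barcode numbers equal the cell numbers stated by the submitters. The median barcode had 3952 and 4206 UMIs, and no barcode had fewer than 500. After filtering, 10379 and 7352 cells were retained, with medians of 4098 and 4199 UMIs and 1460 and 1545.5 detected genes. Thinned to 1000 UMIs per cell, which 8319 and 6952 cells reached, the median was 578 and 565 genes. Because each group is 1 library, no difference below has a replicate check and no test was made. All intervals are 95% intervals that cover counting error only.

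The library labelled KL_Gpx4 held few alveolar macrophages, the resident phagocytes of the air spaces, and few natural killer (NK) cells. Alveolar macrophages made up 5.56% of retained cells in the library labelled KL (577 cells, exact binomial interval 5.13 to 6.02) and 0.721% in the library labelled KL_Gpx4 (53 cells, 0.541 to 0.942), a 7.71-fold lower share. Clustered separately, the second library had 145 such cells (1.97%) and the ratio was 0.35 (0.29 to 0.42). NK cells made up 0.829% (86 cells, 0.663 to 1.02) and 0.109% (8 cells, 0.0470 to 0.214). Several classes had a larger share in the library labelled KL_Gpx4. B cells made up 11.4% (10.8 to 12.0) against 18.0% (17.1 to 18.9), a ratio of 1.57, and plasma cells, which secrete antibody, 0.742% against 1.92%. Neutrophils made up 14.6% (13.9 to 15.3) against 22.1% (21.1 to 23.04), a ratio of 1.51. Type 2 conventional dendritic cells (cDC2), which present antigen to CD4 T cells, made up 1.80% (1.56 to 2.08) against 3.84% (3.41 to 4.30). Their cluster also had Clec9a, a marker of conventional dendritic cells type 1, among its top genes. No class of that type was named, so the cDC2 class may hold both types. Type 2 innate lymphoid cells, a source of interleukins 5 and 13, numbered 21 and 74 cells, a ratio of 4.97. Each class is named for the fixed markers its clusters expressed, so a name means cells like that type.

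T cells made up 26.0% (25.1 to 26.8) of retained cells in the library labelled KL and 32.9% (31.8 to 34.0) in the other, a ratio of 1.27. Within T cells, the regulatory cluster, which suppresses immune responses, made up 6.75% (182 cells, 5.84 to 7.77) and 10.6% (256 cells, 9.40 to 11.9). The shares of the other myeloid classes lay closer together. Non-classical monocytes, which patrol blood vessels, made up 6.64% and 7.28%, classical monocytes, the blood precursors of many tissue macrophages, 4.25% and 4.97%, monocyte-derived or interstitial macrophages 3.93% and 4.11%, and mature dendritic cells 0.684% and 0.816%. Basophils or mast cells made up 0.270% and 0.463%. Cells outside the CD45 gate were also seen, with 0.520% and 1.36% endothelial cells and 10 and 7 epithelial cells.

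**Figure D1:**
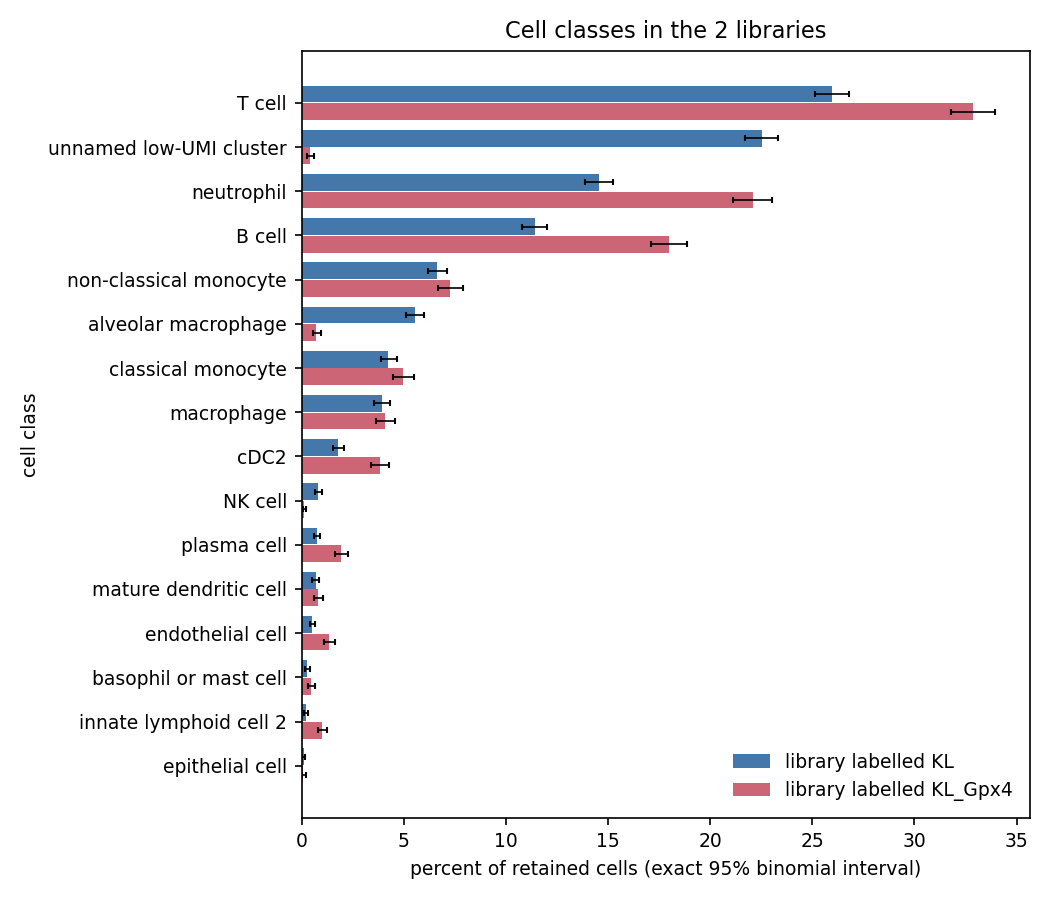
Share of retained cells (percent, x axis) in each cell class (y axis) in the library labelled KL (blue) and the library labelled KL_Gpx4 (red). Bars start at 0 and black lines are exact 95% binomial intervals for counting error only. The unnamed cluster of low UMI count is 22.5% of one library and 0.422% of the other, and alveolar macrophages are 5.56% and 0.721%.

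These shares depend on a cluster that stayed unnamed. It held 2337 cells, or 22.5%, of the library labelled KL and 31 cells, or 0.422%, of the other, with a median of 842 and 771 UMIs per cell. T cell markers stood in this cluster at a median of 28.4% of their level in T cells, alveolar macrophage markers at 24.7%, non-classical monocyte markers at 20.2% and neutrophil markers at 7.77%. As a share of cells in a named class alone, T cells made up 33.5% and 33.0%. That is a ratio of 0.98 (0.93 to 1.04), so their larger share is not seen there. By the same denominator B cells had a ratio of 1.23, neutrophils 1.18, classical monocytes 0.91 (0.79 to 1.05) and alveolar macrophages 0.10. Non-classical monocytes (0.853), monocyte-derived or interstitial macrophages (0.813) and mature dendritic cells (0.928) also fell below 1. Of all retained cells these ratios were 1.096, 1.045 and 1.193. A coarser clustering (Leiden resolution 0.5) placed 363 and 221 cells in the NK class, and its ratio was then 0.86. The T cell class fell to 2419 and 2203 cells there, from 2695 and 2416. That NK class may therefore hold T cells, and its ratio is not one of NK cells alone.

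Each library pooled cells of female and male animals, and the number of animals is not given in the labels. Cells with UMIs of Xist, the RNA that silences an X chromosome in females, and with none of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty made up 15.5% and 14.99% of retained cells. Cells with Y-linked UMIs and no Xist made up 40.7% and 47.4%. The balance differed by class. Among non-classical monocytes, 384 cells had Xist alone and 75 had Y-linked UMIs alone in the library labelled KL, against 74 and 241 in the library labelled KL_Gpx4. Among classical monocytes the numbers were 154 and 173 against 41 and 188. Of all Y-linked cells and of all Xist cells, T cells had share ratios of 0.97 (0.90 to 1.05) and 1.73 (1.52 to 1.97), and B cells 1.16 and 3.64. Neutrophils had 1.11 (0.99 to 1.24) and 2.02 (1.43 to 2.85), so among Y-linked cells their larger share was within counting error. Alveolar macrophages had ratios of 0.0644 and 0.0236, resting on 10 cells and 1 cell of the library labelled KL_Gpx4.

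Gpx4 transcripts were higher, not lower, in the immune cells of the library labelled KL_Gpx4. Over all retained cells Gpx4 (ENSMUSG00000075706) stood at 337 counts per 1000000 UMIs (CPM) in the library labelled KL (exact Poisson interval 333 to 342) and at 614 (606 to 622) in the other. In neutrophils the level was 297 and 959.7 CPM, in T cells 286 and 617 and in non-classical monocytes 298 and 665. In cDC2 it was 282 and 565 CPM, in macrophages 366 and 629, in classical monocytes 508 and 807, in regulatory T cells 545 and 839, and in B cells 192 and 290.3. On the log2 scale these ratios ran from 0.60 in B cells (0.49 to 0.70) to 1.69 in neutrophils (1.62 to 1.77). The 53 alveolar macrophages of the library labelled KL_Gpx4 had 578 CPM (489 to 679), against 604 (582 to 625). These values check nothing about the labels, since the loss of Gpx4 is placed in tumour cells and the sort took CD45-positive cells. The few epithelial cells had 228 Gpx4 UMIs in 10 cells (886 CPM, 774 to 1008) in the library labelled KL and 26 UMIs in 7 cells (296 CPM, 194 to 434) in the other. Whether these epithelial cells are tumour cells was not determined.

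**Figure D2:**
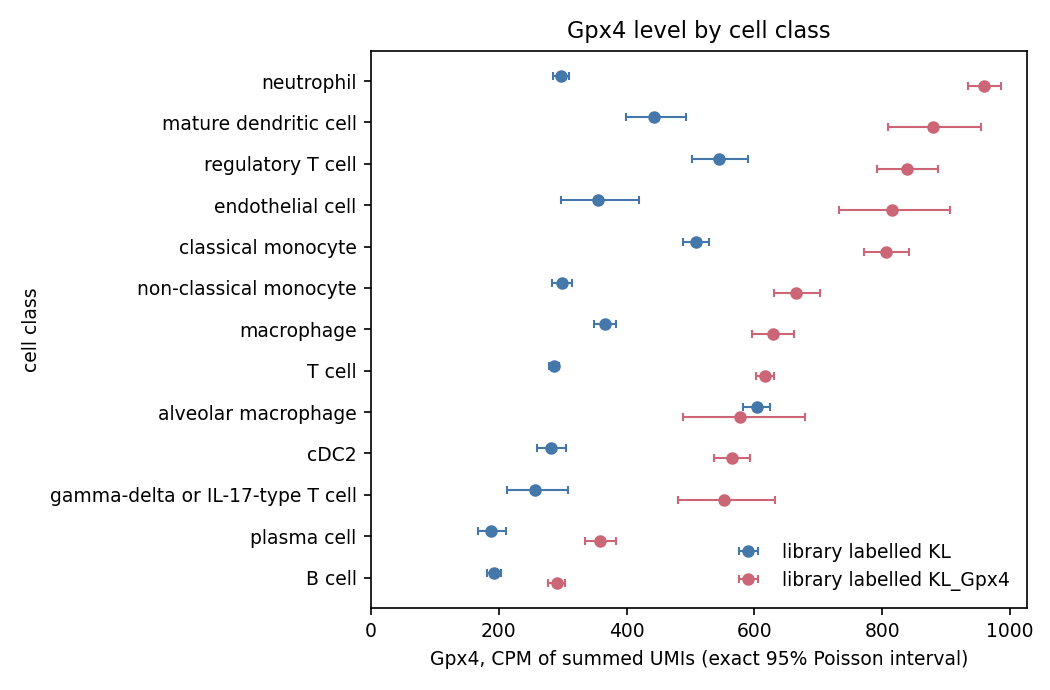
Gpx4 level in CPM of summed UMIs (x axis, starting at 0) by cell class (y axis, classes with 50 or more cells in each library) in the library labelled KL (blue) and the library labelled KL_Gpx4 (red). Lines are exact 95% Poisson intervals for counting error only. Gpx4 is higher in the library labelled KL_Gpx4 in every class drawn except alveolar macrophages (604 and 578 CPM), and reaches 959.7 CPM in neutrophils.

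The genes next to Gpx4 on chromosome 10 were higher with it. In the GRCm38 build (mm10) Gpx4 is a protein-coding gene at 80047166 to 80056439 on the plus strand. Sbno2, a transcriptional co-regulator at 80056992 to 80105571, had a median log2 ratio of 1.95 over the 7 main cell classes. Stk11, the Lkb1 gene, which is floxed in both groups and starts 59.4 kb beyond the end of Gpx4 (80115803 to 80130682), had a median of 1.25. Cbarp, a regulator of calcium channels at 80130451 to 80140835, had 2.82. Midn had 0.97, Abca7, a lipid transporter, 0.84, Arhgap45 0.74, Cirbp, a cold-inducible RNA-binding protein, 0.58 and Tmem259 0.54. Of the 12 measured genes from Tmem259 (start 79974948) to Cirbp (end 80172786), the other 3 stood near 0, with medians of -0.14 for Polr2e, 0.11 for Atp5d and 0.00 for Cnn2. The annotated ends of Stk11 and Cbarp overlap on opposite strands, and whether counting used the strand is not given in the sources used here, so their values are uncertain.

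**Figure D3:**
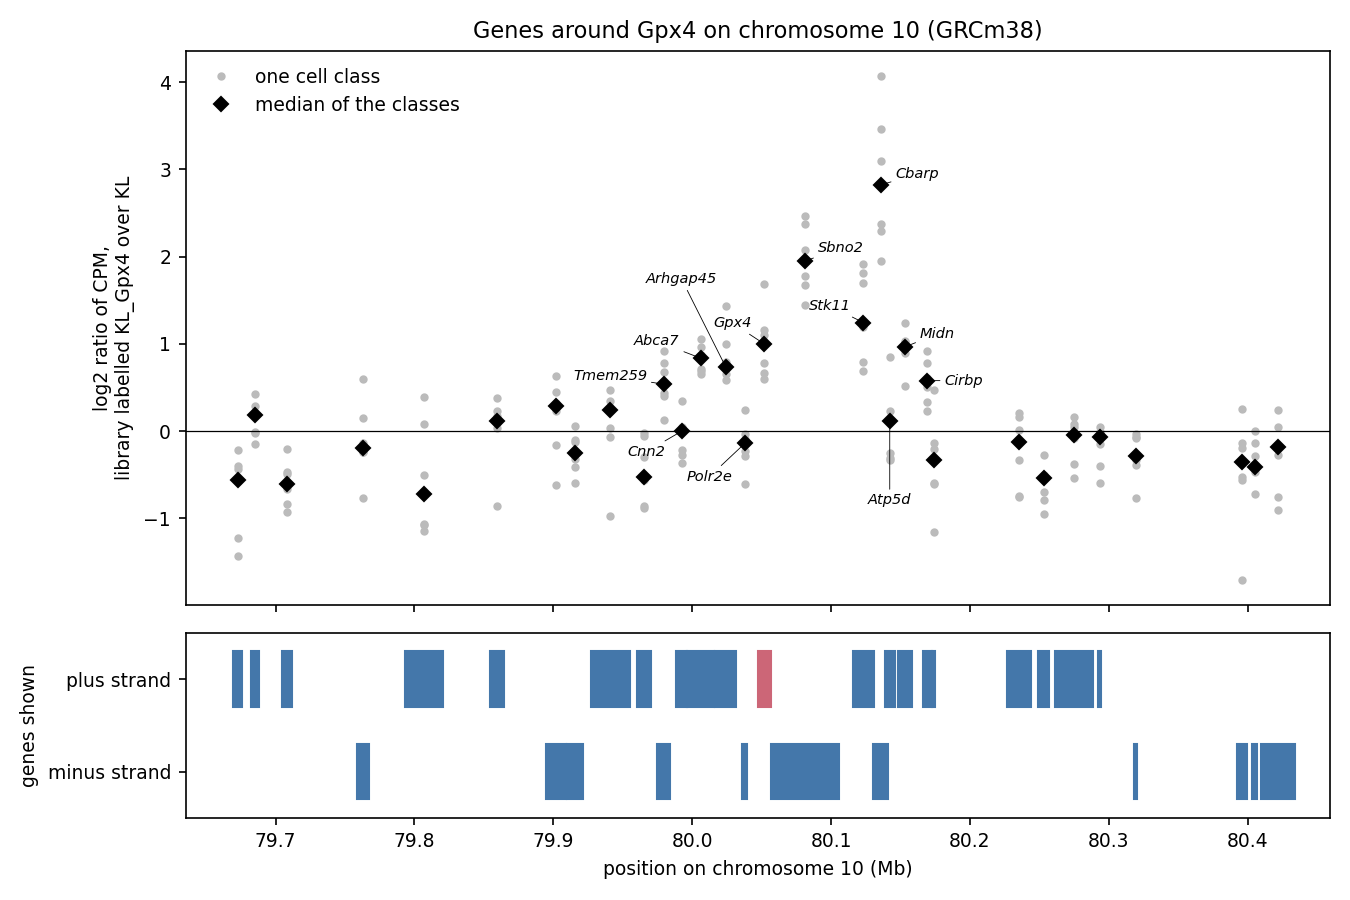
Upper panel: log2 ratio of CPM, library labelled KL_Gpx4 over library labelled KL (y axis), of each measured gene within 400000 bases of Gpx4 by its position on chromosome 10 in Mb (x axis, GRCm38); grey points are the 7 cell classes and black diamonds their median. Lower panel: the same genes to scale on each strand, with Gpx4 in red. The raised genes run from Tmem259 to Cirbp with medians from 0.54 to 2.82, and Cnn2, Polr2e and Atp5d lie between them near 0.

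The wider ferroptosis and glutathione list showed no common direction across classes. In classical monocytes 9 of its 26 measured members were higher by 1.5-fold or more and 1 was lower, with a median log2 ratio of 0.35 (counting interval 0.10 to 0.44). That median stood at the 99.31 percentile of random lists matched on size and expression, but was -0.06 with each cell thinned to 1000 UMIs. In non-classical monocytes 11 of 27 were higher and 4 lower, with a median of 0.29 after subtracting the median of all genes (97.00 percentile). The medians were -0.08 in T cells, 0.07 in regulatory T cells, -0.18 in B cells (3 of 24 higher, 4 lower), 0.06 in macrophages and -0.15 in cDC2. In neutrophils the median was -0.07, or 0.29 relative to the median of all genes (80.61 percentile), and above 0 with both other scalings of the UMI sums. With one doublet threshold in both libraries the relative median was 0.07.

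Interferon-stimulated genes were lower in the library labelled KL_Gpx4 in most classes. The type I interferon list, which holds antiviral genes that all cells induce on sensing interferon, had a median log2 ratio of -0.65 in B cells (13 of 22 lower by 1.5-fold or more, 0 higher). In classical monocytes it was -0.76 (17 of 27 lower, 1 higher), in T cells -0.40 (7 of 28 lower, 0 higher) and in regulatory T cells -0.60 (9 of 17 lower, 0 higher). In cDC2 the median was -0.51 (9 of 21 lower, 1 higher) and in macrophages -0.49 (10 of 25 lower, 4 higher). In non-classical monocytes it was -0.65 relative to the median of all genes (10 of 22 lower, 2 higher). Each of these 7 medians stood at or under the 0.10 percentile of its matched random lists. In neutrophils the median was -0.37 (10 of 27 lower, 3 higher), but all genes had a median of -0.36 there, and the list stood at the 22.16 percentile. In the largest neutrophil cluster alone it was -0.62 relative to all genes.

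Genes that load and present peptides on MHC class I, many of them also induced by interferon, were lower in several classes. The list's 16 genes were all measured. The median was -0.36 in T cells, -0.43 in regulatory T cells, -0.38 in B cells and -0.34 in macrophages, and -0.75 relative to all genes in non-classical monocytes, each under the 1 percentile of matched lists. It was -0.37 in classical monocytes (5.44 percentile), -0.16 in cDC2 (8.19 percentile) and -0.27 in neutrophils (19.75 percentile), where it turned to 0.04 with median-of-ratios scaling.

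**Figure D4:**
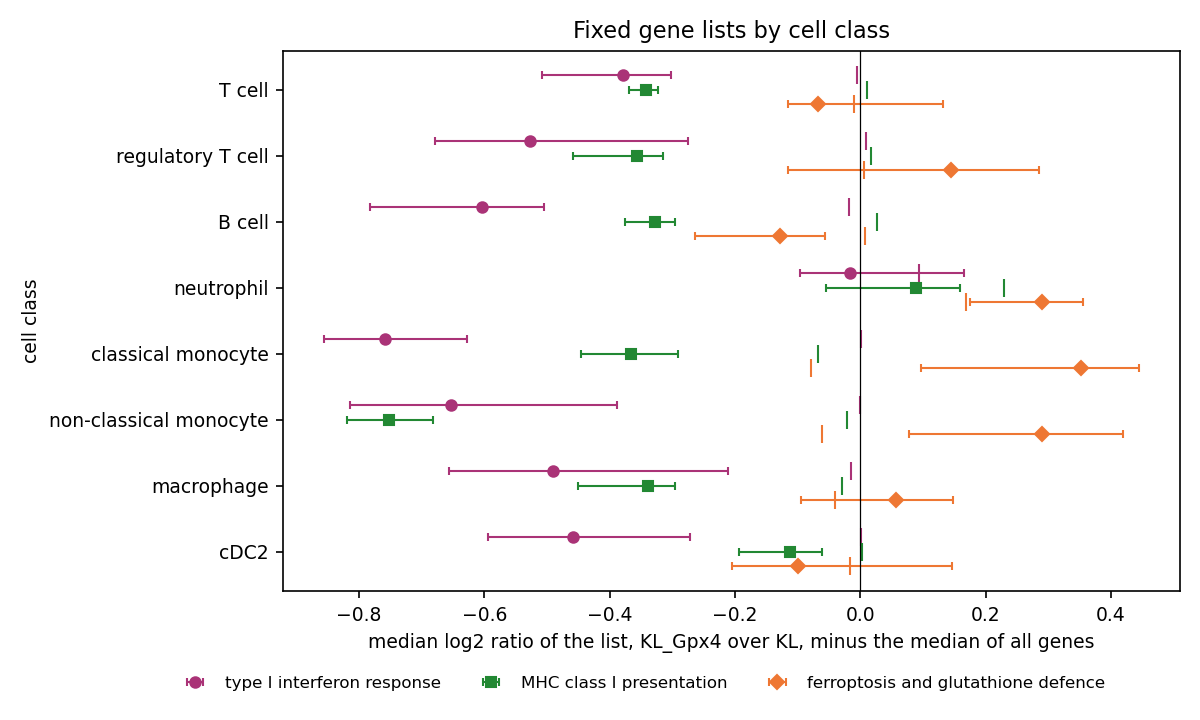
Median log2 ratio, library labelled KL_Gpx4 over library labelled KL, of 3 fixed gene lists minus the median of all genes (x axis) in 8 cell classes (y axis); horizontal lines are counting intervals and short vertical ticks mark the median of matched random lists. The type I interferon list lies left of its tick in all 8 classes, at -0.76 in classical monocytes, -0.38 in T cells and -0.02 in neutrophils. The ferroptosis and MHC class I medians of neutrophils change sign with another scaling before this subtraction.

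T cells of the library labelled KL_Gpx4 had more transcripts of regulatory and checkpoint genes and fewer of cell division genes (2695 and 2416 cells). Of the 19 regulatory T cell effector genes 7 were higher by 1.5-fold or more and 0 lower, with a median log2 ratio of 0.32 (0.24 to 0.39, 99.85 percentile). Il1rl1, the receptor for interleukin 33, stood at 44.4 and 107 CPM, a fold of 2.41. Il2ra, a chain of the interleukin 2 receptor, was 1.71-fold higher, and Foxp3, the defining transcription factor of regulatory T cells, 1.55-fold (log2 0.64, 0.45 to 0.82). The regulatory cluster's own share of T cells was 1.57 times as large, as given above. Of the 16 exhaustion and checkpoint genes 3 were higher and 1 lower, with a median of 0.30 (99.73 percentile). Tnfrsf9, the costimulatory receptor 4-1BB, was 1.57-fold higher, and Rgs16, a regulator of G protein signalling, 1.92-fold. Klrg1, a receptor of differentiated effector cells, was 1.70-fold higher. Il1rl1, Foxp3, Il2ra, Tnfrsf9 and Klrg1 were all among the top genes of the regulatory cluster. Its larger share was not separated from a change within other T cells.

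Of the 22 cell cycle genes 9 were lower in T cells and 0 higher, with a median of -0.54 (-0.60 to -0.49, percentile 0). A dividing cluster with Mki67, Top2a and Birc5 among its top genes made up 2.75% and 1.99% of T cells. Rrm2, which makes DNA precursors, stood at 28.3 and 13.7 CPM. Among chemokines 6 of 20 were lower and 5 higher, with a median of -0.32. Xcl1, which attracts cross-presenting dendritic cells, was 5.51-fold lower (89.8 and 16.3 CPM). Psmb8, an immunoproteasome subunit, was 1.86-fold lower, H2-T22, a class I heavy chain, log2 -0.73, and Bst2, an interferon-induced antiviral membrane protein, 1.64-fold lower. Ly6c2, a surface protein of memory and effector CD8 cells, was 2.25-fold lower and Dapl1, a gene of naive CD8 cells, 2.03-fold lower, but CD8 cells were also a smaller part of the class. A cluster with Cd8b1, Cd8a, Dapl1 and Lef1 among its top genes made up 18.0% and 13.3% of T cells, and Cd8a and Cd8b1, chosen after their values were seen, had log2 ratios of -0.78 and -0.80. S1pr1, the receptor that guides exit from lymphoid organs, was 1.68-fold higher. By size, Cbarp (5.18-fold), Sbno2 (3.20-fold), Cdk8, a kinase of the Mediator complex (836 and 2509 CPM), and the noncoding RNA Gm19951 (2.80-fold) were higher. All of these were higher in each of the 7 main classes, so none is particular to T cells. The heat shock protein gene Hspa1a was 3.73-fold lower. Lyz2, a lysozyme of myeloid cells that T cells do not make, stood at 942 and 301 CPM in T cells. It can come from free RNA or from doublets with myeloid cells, which remain in the library labelled KL. The epithelial list had a median of -1.07 (5 of 8 lower, 2 higher). In cells with Xist alone, Foxp3 (-0.32), Klrg1 (-0.04) and the effector list (-0.01) lay below 0 and the checkpoint list stood at 0.10. With each cell assigned without clusters the effector list stood at 0.08 and the checkpoint list at 0.12.

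Within the regulatory T cell cluster (182 and 256 cells), the effector list as a whole stood near 0. Its median log2 ratio was -0.09 (45.39 percentile), with 2 of 19 genes higher and 1 lower. Il2ra (356 and 744 CPM, fold 2.09) and Il1rl1 (514 and 825 CPM, fold 1.61) were higher there too. Havcr2, the checkpoint receptor TIM-3, rested on 41 and 109 UMIs, a fold of 2.05 (log2 1.04, 0.51 to 1.59). Gpx4 was 1.54-fold higher, Sbno2 3.02-fold and Midn, a regulator of protein degradation, 2.74-fold. Psmb9, an immunoproteasome subunit, was 2.17-fold lower, Isg20, an interferon-induced nuclease, 1.97-fold lower, and Mki67, a marker of dividing cells, 2.76-fold lower (98 and 46 UMIs), though the cell cycle list stood near its random lists (median -0.06, 4 of 17 lower, 1 higher, 54.96 percentile). With doublet calls kept that list was -0.56. Chemokines were lower (7 of 9, 0 higher, median -0.93, percentile 0), as was the dissociation and immediate early list (6 of 23 lower, 1 higher, median -0.39, percentile 0). Lyz2 was lower in the T cell class that holds this cluster. Free RNA and doublets were not separated from a difference in these cells.

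B cells of the library labelled KL_Gpx4 had lower interferon and cell division genes (1185 and 1321 cells), and transcripts of other cell types were lower in them as well. All 22 measured type I interferon genes lay below 0. Stat1, the signal transducer of interferon receptors, was 1.60-fold lower (111 and 69.5 CPM), Ifi27l2a 2.00-fold lower (319 and 160 CPM), Bst2 1.52-fold and Psmb8 1.77-fold lower. Of the 22 cell cycle genes 7 were lower and 0 higher (median -0.46, percentile 0), among them Cdk1, the kinase that drives mitosis, 2.09-fold lower. All 24 nuclear genes of oxidative phosphorylation lay below 0, with a median of -0.29 (-0.33 to -0.26, 0.04 percentile), though 1 of them passed 1.5-fold, while 12 of the 13 mitochondrially encoded genes lay above 0 (median 0.15, 2 higher by 1.5-fold, 0 lower). The B cell activation and germinal centre list stood near its random lists (median -0.11, 19.50 percentile). Its member Ighm, the heavy chain of IgM, stood at 2883 and 1466 CPM. Sfn, the adaptor 14-3-3 sigma, was 3.14-fold higher and Sbno2 4.21-fold. Zfp36l2, an mRNA decay factor, was 2.78-fold lower and Hspa1a 3.63-fold lower. Lists of other cell types had medians below or near that of the interferon list. They were -1.33 for the cytotoxic effector list (12 of 17 lower, 0 higher), -0.83 for complement and -0.74 for regulatory T cell effector genes. Granule-rich neutrophil genes had -0.64 and the myeloid suppressor list -0.61. Lyz2, again a sign of free RNA or of doublets with myeloid cells, stood at 1129 and 245 CPM. The iron storage chains Ftl1 and Fth1, 2.01-fold and 1.60-fold lower, stood at 10.7% and 13.1% of their level in the top class, so free RNA was not separated from a difference in B cells. With one doublet threshold in both libraries the cytotoxic list was -0.83 and the regulatory list 0.01. In cells with Xist alone (74 and 184 B cells) Stat1 (0.18), Cdk1 (0.35) and the cell cycle list (0.35) lay above 0.

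Neutrophils of the library labelled KL_Gpx4 had fewer transcripts of the Siglec-F-high programme of tumour-associated neutrophils (1513 and 1623 cells), and the class was made up of different clusters in each library. A cluster with Siglecf, Ccl3 and Il1rn among its top genes made up 32.0% of neutrophils in the library labelled KL (484 cells) and 7.27% in the other (118 cells). A cluster with Camp, Ngp and Ltf made up 7.47% and 2.34%, and the largest cluster 60.5% and 90.4%. The median log2 ratio of all measured genes was -0.36, so gene values are given relative to it. Counts of members past 1.5-fold are not, and so lean to the lower side. Of the 24 programme genes 11 were lower by 1.5-fold or more and 0 higher, with a median of -0.53, or -0.18 relative to all genes (percentile 0 of matched lists). Siglecf, a sialic acid receptor, was -2.27 relative to all genes (87.3 and 14.1 CPM). Hexb, a lysosomal enzyme, was -1.64, Xbp1, a factor of the unfolded protein response, -1.17, Ltc4s, the leukotriene C4 synthase, -1.13, and Ccl3, a chemokine, -0.90 (3298 and 1386 CPM). In the largest cluster alone (916 and 1467 cells), whose genes had a median of 0.11, the relative values were -0.24 for the list, -0.12 for Ltc4s, -1.18 for Siglecf and -1.25 for Xbp1. With doublet calls kept in both libraries the median of all genes was -0.13 and the relative list median -0.50, and with one doublet threshold -0.17 and -0.48.

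The hypoxia and glycolysis genes were also lower in neutrophils, with 9 of 21 lower, 1 higher and a median of -0.55, or -0.19 relative to all genes (0.05 percentile). Egln3, an oxygen-sensing hydroxylase, was -1.49 relative to all genes, Bnip3, a mitophagy receptor, -0.88, and Mif, a cytokine, -0.71. The dissociation and immediate early list had 12 of 23 genes lower and 0 higher, with a median of -0.62, or -0.26 relative to all genes (percentile 0). The 12 measured mitochondrially encoded genes were higher, with a median of 1.003 relative to all genes and 7 past 1.5-fold. The granule-rich neutrophil list had a median of 0.24, or 0.59 relative to all genes (3 of 20 higher, 2 lower, 97.69 percentile). Its members went both ways, with Retnlg, a resistin-like secreted protein, at 1.10 relative to all genes, Padi4, the enzyme of extracellular trap formation, at 1.20, and Camp, the antimicrobial cathelicidin, at -0.37. In the largest cluster alone that list was -0.45 and Retnlg -0.16 relative to the genes of that cluster. By size, Srxn1, which repairs oxidised peroxiredoxins, was 2.86 above all genes (23.4 and 133 CPM), Rdh12, a retinol dehydrogenase, 2.75, Sbno2 2.73 and Stk11 2.27. Cish, a suppressor of cytokine signalling, was -1.65, Hspa1a -1.80 and the peroxidase Prdx1 -0.57. Transcripts of other cells were lower as well, with relative medians of -1.04 for the cytotoxic effector list (14 of 18 lower, 3 higher) and -0.89 for the naive and memory T cell list (11 of 15 lower, 0 higher). With one doublet threshold in both libraries these were -0.57 and 0.27. The cell cycle list was -1.13 relative to all genes (15 of 19 lower, 0 higher, percentile 0), but -0.10 in the largest cluster alone. The alternatively activated or tumour-associated macrophage list was 0.60 relative to all genes (6 of 19 higher, 3 lower, 99.81 percentile).

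Classical monocytes of the library labelled KL_Gpx4 had higher inflammatory and tissue-repair genes and lower cell division genes (441 and 365 cells). Of the 18 measured genes of alternatively activated or tumour-associated macrophages 11 were higher by 1.5-fold or more and 1 lower, with a median log2 ratio of 1.30 (0.86 to 1.48, percentile 100). Vegfa, the vascular growth factor, was 4.50-fold higher (32.9 and 148 CPM), Spp1, osteopontin, 3.05-fold, and the eosinophil chemokine Ccl24 had 5 and 78 UMIs, a log2 ratio of 4.90 (3.61 to 6.56). Of the 20 NF-kB and cytokine genes 11 were higher and 2 lower (median 0.69, 99.94 percentile). Tnf was 4.51-fold higher, Il1a 3.69-fold, the neutrophil attractant Cxcl1 6.72-fold and the monocyte attractant Ccl2 2.33-fold, while Il1b was 1.79-fold lower (3768 and 2107 CPM). Chemokines had a median of 0.50 (6 of 15 higher, 1 lower) and the granule-rich neutrophil list -0.60 (10 of 19 lower, 2 higher).

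Some genes of the ferroptosis and glutathione list were higher in these monocytes. Slc7a11, the cystine importer that feeds glutathione synthesis, was 3.36-fold higher (59.3 and 199 CPM), Srxn1 3.78-fold, Txnrd1, a thioredoxin reductase, 1.91-fold and Gclc, the first enzyme of glutathione synthesis, 2.24-fold (69 and 81 UMIs), while Prdx1 was 1.86-fold lower. Of 21 cell cycle genes 16 were lower and 1 higher, with a median of -1.19 (percentile 0), among them Tubb5, a tubulin, 2.83-fold lower. All 12 measured mitochondrially encoded genes were higher by 1.5-fold or more (median 1.01). By size, Efr3b, a membrane scaffold of phosphoinositide kinase (4.30), Egr1, an immediate early factor (3.78), and Flnb, an actin cross-linker (3.23), were among the genes with high log2 ratios, and Socs3, an inhibitor of cytokine signalling (-1.68), Id1 (-1.62) and Hspa1a (-1.71) among those with low ones. Efr3b was higher by 1 or more in all 6 main classes where it was measured, so it is not particular to these monocytes. The dissociation and immediate early list, which holds Egr1, had a median of 0.18 (5 of 23 higher, 4 lower, 98.91 percentile). The interferon-induced genes Phf11b and Rtp4 were 2.94-fold and 2.81-fold lower. Per cell, monocytes of the library labelled KL had a median of 11267 UMIs and those of the other 6571. Thinned to 1000 UMIs per cell, the macrophage list had a median of 0.14 over 11 genes and the ferroptosis list -0.06. With each cell assigned without clusters the macrophage list had a median of 0.01, and in cells with Xist alone Gclc was -0.13. The cell cycle list was -0.38 thinned and -0.20 in cells with Xist alone.

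Non-classical monocytes of the library labelled KL_Gpx4 had lower class I and respiratory chain genes (689 and 535 cells). The median of all genes was 0.14, and values are relative to it, apart from counts of members past 1.5-fold. The median cell had 6195 and 3469 UMIs. Saa3, an acute-phase serum amyloid, had 2138 and 23 UMIs, a relative log2 ratio of -5.38, but was detected in 10.6% and 3.36% of the cells. Hp, haptoglobin, was -2.69 and Plac8 -2.54. Both are fixed markers of classical monocytes, detected in 88.7% and 39.1% (Hp) and 91.4% and 62.1% (Plac8) of the cells. A different mix of monocytes in this class was not separated from a change within it. Ifi27l2a was -2.00, H2-Q7, a class I heavy chain, -1.47, and B2m, the class I light chain, -1.07 (7139 and 3747 CPM). Of the 24 nuclear genes of oxidative phosphorylation 18 were lower by 1.5-fold or more and 0 higher (relative median -0.81, 0.01 percentile), with Cox5a, of cytochrome c oxidase, at -1.23 and Sdhd, of succinate dehydrogenase, at -1.24. The 12 mitochondrially encoded genes went the other way, with a relative median of 0.58 and 9 past 1.5-fold. Lists of other cell types were lower too, with relative medians of -1.58 for cytotoxic effector genes (7 of 11 lower, 1 higher), -1.24 for naive and memory T cell genes (7 of 13 lower, 2 higher) and -1.25 for epithelial genes (3 of 5 lower, 2 higher). With one doublet threshold in both libraries the first was -0.37 and the next 0.28.

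Among 26 lipid handling genes in non-classical monocytes 11 were higher and 6 lower, with a relative median of 0.17 (85.24 percentile). Pparg, a nuclear receptor of lipid metabolism, was 1.80 above all genes (149 and 572 CPM) and Plin2, a coat protein of lipid droplets, 1.05. Gclc (1.26) and Gss (0.98), the enzymes of glutathione synthesis, were higher with Gpx4 (1.02). By size, Gdf15, a stress-induced cytokine, was 2.92 above all genes, P2rx7, the ATP-gated channel that activates the inflammasome, 2.63 and Egr1 2.38. P2rx7 was higher by 1 or more on the log2 scale in 6 of the 7 main classes, so it is not particular to this one. As given above, most cells with 1 kind of sex-linked UMI alone had Xist in one library and Y-linked UMIs in the other, and 26.6% and 38.7% of the class had neither. Relative to all genes of each fraction, Saa3 was 0.53 (-0.87 to 2.15) in the Y-linked cells, and the lipid list had a median of -0.13 in the Xist cells.

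Monocyte-derived or interstitial macrophages of the library labelled KL_Gpx4 had fewer cell division and glycolysis transcripts and more of some alternative activation genes (408 and 302 cells). Of the 21 hypoxia and glycolysis genes 12 were lower by 1.5-fold or more and 0 higher, with a median log2 ratio of -0.69 (-0.86 to -0.54, percentile 0). Of the 21 cell cycle genes 14 were lower and 0 higher (median -1.11, percentile 0; -0.28 with each cell thinned to 1000 UMIs). The 24 nuclear genes of oxidative phosphorylation all lay below 0 (median -0.39, 4 lower by 1.5-fold, 0.02 percentile). The dissociation and immediate early list had a median of 0.20 (5 of 23 higher, 0 lower, 99.40 percentile) and the epithelial list, a sign of free RNA, -1.07 (4 of 6 lower, 2 higher). The glycolytic enzymes Gapdh (937 and 464 CPM) and Ldha were 2.02-fold and 1.87-fold lower. The alternatively activated or tumour-associated list stood near 0 as a whole (median 0.04, 7 of 22 higher, 4 lower). Within it Chil3, a chitinase-like protein, was 7.15-fold higher (239 and 1711 CPM), Ccl24 6.53-fold, the fatty acid receptor Cd36 2.94-fold and Arg1, arginase 1, 2.12-fold. Ccl24 was detected in 10.3% and 12.6% of the cells and Arg1 in 16.9% and 15.6%, so few cells carried them. Chil3 was detected in 59.8% and 63.9%, and it is also a fixed marker of alveolar macrophages. Clustered separately, the library labelled KL_Gpx4 had 145 of those cells, against 53. With under 100 cells there, that class was left out of the limit against free RNA. Alveolar macrophages or their free RNA were not separated from a difference in this class. Of the 20 NF-kB and cytokine genes 6 were higher and 3 lower (median 0.11, 89.09 percentile), with Il6 3.15-fold and Il1b 2.10-fold lower. Lpl, lipoprotein lipase, was 3.52-fold lower, and the interferon-induced nucleic acid sensor Zbp1 2.77-fold lower. By size, Prtn3, a neutrophil granule protease (338 and 20 UMIs), Lrg1 and Clec4n, a lectin receptor for fungi, were 8.36-fold, 3.77-fold and 3.72-fold lower. Sbno2 was 3.43-fold and Txnrd1 1.75-fold higher. The 12 measured mitochondrially encoded genes had a median of 0.43 (4 higher, 0 lower), and the median cell had 10164 and 6569.5 UMIs. In cells with Xist alone (89 and 84 cells) the hypoxia list had a median of -0.12.

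Type 2 conventional dendritic cells of the library labelled KL_Gpx4 had fewer chemokine and complement transcripts (187 and 282 cells). As given above, the class may hold conventional dendritic cells type 1 too, and a different mix of the types was not separated from the differences below. Of 16 chemokines 9 were lower and 3 higher, with a median log2 ratio of -0.72 (-0.94 to -0.46, percentile 0). Ccl22, which attracts regulatory T cells, was 2.43-fold lower and Cxcl2, which attracts neutrophils, 2.37-fold lower, while Ccl24 had 12 and 210 UMIs (log2 3.78, 2.95 to 4.76). Of 9 complement genes 5 were lower and 0 higher (median -0.996). C1qa and C1qc, chains of the C1q complex that macrophages make, stood at 276 and 40.7 CPM and at 158 and 15.8 CPM. In the library labelled KL these levels were 8.00% and 5.91% of those in the class with the highest level, and that of Cxcl2 2.54%, all under the 10% limit used against free RNA. The dissociation and immediate early list had a median of -0.16 (5 of 23 lower, 2 higher, 5.29 percentile), with Hspa1a 6.95-fold and Hspa1b 9.57-fold lower. Isg15, an interferon-induced ubiquitin-like modifier, was 2.47-fold lower, Bst2 1.53-fold, Il1b 2.32-fold and Fth1 1.87-fold lower. The hypoxia and glycolysis list had a median of -0.36 (4 of 21 lower, 1 higher, percentile 0), and the cell cycle list -0.39 (8 of 21 lower, 4 higher), which turned with means of per-cell CPM (0.10). The 12 measured mitochondrially encoded genes had a median of 0.51 (5 higher, 0 lower, 99.96 percentile). By size, Sbno2 (1.95), Tpcn1, an endolysosomal channel (2.21), and Wnt11, a secreted Wnt ligand (2.11), had high log2 ratios, and Prkca, a protein kinase C, was 6.24-fold lower. In the 30 and 42 cells with Xist alone C1qa (1.06), C1qc (0.85), Ccl22 (2.21), Cxcl2 (0.77) and both lists (0.10 and 0.44) lay above 0, and Bst2 was 0.10 there and without clusters. With one doublet threshold in both libraries the chemokine list was -0.12 and the complement list -0.52.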

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

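All comparisons in this part were chosen after the data were examined. Cells were split by whether they had UMIs of Xist and none of the Y-linked genes, or the reverse, and the shares here are of the cells of each fraction in a named class. These results stand out because the difference between the libraries runs one way in one fraction and the other way in the other. With 1 library per group this difference between the fractions was not tested.

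The share of T cells was higher in the library labelled KL_Gpx4 among cells with Xist alone and lower among cells with Y-linked UMIs alone. In the first fraction T cells made up 31.7% (429 cells) in the library labelled KL and 46.0% (507 cells) in the other, a ratio of 1.45 (counting interval 1.27 to 1.66). In the second they made up 40.4% (1572 cells) and 36.3% (1263 cells), a ratio of 0.90 (0.83 to 0.97). As a share of all cells of the fraction, unnamed ones included, the ratios were 1.73 (1.52 to 1.97) and 0.97 (0.90 to 1.05), so the lower share in the second fraction depends on the denominator.

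Non-classical monocytes made up 28.4% (384 cells) and 6.72% (74 cells) of the cells with Xist alone, a ratio of 0.24 (0.18 to 0.30). Of the cells with Y-linked UMIs alone they made up 1.93% (75 cells) and 6.92% (241 cells), a ratio of 3.59 (2.76 to 4.72). Over all retained cells the shares were 6.64% and 7.28%. As a share of all cells of the fraction, unnamed ones included, the ratios were 0.28 and 3.89. Each fraction leaves out the cells with neither kind of UMI, 40.9% and 35.6% of retained cells, so a class of shallow cells is under-counted in both.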

How the results depend on the processing

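The single doublet threshold, the named-class denominator, the fractions of cells by Xist and Y-linked UMIs, the largest neutrophil cluster alone and the gene numbers without thinning were chosen after the data were examined. Over all alternatives, 1886 of 1902 gene values, 1081 of 1111 list values and 148 of 158 share ratios with a direction to keep kept it. Most of these genes were named for the size of their ratio, and the lists were picked after values were seen. The alternatives reuse the same 2 libraries, so most values were bound to keep their direction. These counts do not show how the results would repeat in other animals. Gpx4 stayed above 0 under every alternative in each class with 100 or more cells per library. No paired analysis was possible because each group has 1 library. Some alternatives gave no value. Separate clustering gave none for regulatory T cells, cDC2, NK cells, innate lymphoid cells, mature dendritic cells and epithelial cells, and assignment without clusters none for regulatory T cells. Mature dendritic cells had none at Leiden resolution 0.5, epithelial cells none over all barcodes and Prtn3 in macrophages and the complement and regulatory lists of B cells none in cells with Xist alone, and the epithelial list of non-classical monocytes none thinned, at 100 UMIs or in Y-linked cells. Depth limits the genes with few UMIs, and cells under 1000 UMIs leave the thinned values. In the values below, shares are ratios, genes and lists are log2 ratios without subtraction of the median of all genes, and the cause was not tested.

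With the stricter cell filter the share ratios were 1.18 for T cells, 0.0918 for alveolar macrophages and 1.38 for neutrophils. With doublet calls kept the Siglec-F neutrophil list was -0.63, and with one doublet threshold -0.65, and the naive and memory T cell list of neutrophils (0.16 and 0.099) and of non-classical monocytes (0.00086 and 0.45) turned, as did the regulatory list of B cells with that threshold (0.0076). Leiden resolution 0.5 gave 0.86 for NK cells, a class that may hold T cells there. Separate clustering gave 1.14 for T cells and 0.35 for alveolar macrophages. With each cell assigned without clusters the ratios were 1.12 for T cells, 0.0924 for alveolar macrophages and, turned, 0.49 for classical monocytes. The interferon list was then -0.90 in B cells, the checkpoint list 0.12 in T cells, the Siglec-F list -0.62 and in cDC2 Bst2 (0.10) and the cell cycle list (0.43) turned. Among cells other than neutrophils B cells had 1.73 and T cells 1.39. Among cells in a named class B cells had 1.23 and neutrophils 1.18. T cells (0.98, 0.93 to 1.04) and classical monocytes (0.91, 0.79 to 1.05) turned, but both lay within counting error of 1. Non-classical monocytes (0.853), macrophages (0.813) and mature dendritic cells (0.928) fell below 1 too. Their main ratios lay within counting error, so they had no direction to keep.

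TMM scaling gave 1.94 for Gpx4 and -0.28 for the Siglec-F list in neutrophils and turned the ferroptosis list there to 0.19. Median-of-ratios scaling gave 2.00 and -0.22 and turned the ferroptosis list (0.25) and the MHC class I list (0.043) of neutrophils. The median of all genes moved with TMM to -0.10 in neutrophils, -0.13 in non-classical and -0.16 in classical monocytes, and with median-of-ratios scaling to -0.05, -0.16 and -0.13. In neutrophils it also moved to -0.13 with doublet calls kept, -0.17 with one doublet threshold and 0.11 in the largest cluster alone, and every relative neutrophil value rests on it. Means of per-cell CPM gave 0.75 for Gpx4 and -0.83 for the interferon list in B cells, and -0.68 for the Siglec-F list, and turned the mitochondrially encoded list of B cells (-0.029) and the cell cycle list of cDC2 (0.10). Thinned to 1000 UMIs, Gpx4 was 1.20 in T cells and 1.77 in neutrophils, the Siglec-F list -0.63 and the ferroptosis list of classical monocytes (-0.061), the cell cycle list of cDC2 (0.35) and the cytotoxic list of non-classical monocytes (0.087) turned. Detected genes per cell were 347 and 330 at 500 UMIs and 1460 and 1546 without thinning.

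Of all cells with Y-linked UMIs alone the share ratios were 1.16 for B cells, 0.0644 for alveolar macrophages and 1.11 (0.99 to 1.24) for neutrophils. T cells turned within counting error (0.97, 0.90 to 1.05). Of those in a named class these 4 ratios were 1.08, 0.0595, 1.02 (0.91 to 1.14) and 0.90. That changes the denominator too, which alone takes T cells to 0.98. In the Y-linked cells Gpx4 in neutrophils was 1.54, and Camp in neutrophils (0.079) and Saa3 (0.65) and the cytotoxic list (0.20) in non-classical monocytes turned. Of all cells with Xist alone the ratios were 3.64 for B cells, 1.73 for T cells, 0.0236 for alveolar macrophages and 2.02 for neutrophils, and basophils or mast cells (0.49) and classical monocytes (0.39) turned. Of those in a named class they were 3.06, 1.45, 0.0198, 1.69, 0.41 and 0.33, and endothelial cells turned (0.85). In B cells of that fraction Gpx4 was 0.72, and Cdk1 (0.35), Stat1 (0.18) and the cell cycle list (0.35) turned. In its T cells the interferon list was -0.61 and the checkpoint list 0.10, and Foxp3 (-0.32), Klrg1 (-0.042) and the regulatory effector list (-0.014) turned. In its cDC2 Bst2 (0.10), C1qa (1.06), C1qc (0.85), Ccl22 (2.21), Cxcl2 (0.77) and the chemokine (0.10), complement (0.44), cell cycle (1.22) and hypoxia (0.22) lists turned. In its neutrophils the Siglec-F list was -0.11, and Prdx1 (0.83), Retnlg (-0.38) and the ferroptosis (0.27), granule-rich (-0.82) and naive and memory T cell (0.18) lists turned. Gclc in classical (-0.13) and the lipid (-0.027) and naive and memory T cell (0.064) lists in non-classical monocytes turned too. In the largest neutrophil cluster alone Gpx4 was 1.78 and the Siglec-F list -0.13, and Retnlg (-0.049) and the ferroptosis (0.18), granule-rich (-0.33), naive and memory T cell (0.014) and cell cycle (0.012) lists turned.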

Other observations

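The tests below were chosen after the result was seen, except the alveolar macrophage markers over all cells and the interferon list without its top cells. A small set of genes differed in the same direction in nearly every class. On the log2 scale 21 genes were higher by 1 or more in the library labelled KL_Gpx4 in at least 6 of the 7 main classes, and 11 were lower. Arg1, an enzyme of alternatively activated macrophages, was higher in all 7 (median 2.31). It stood at 12.9 CPM in T cells and 6.53 in B cells of that library against 567 in macrophages, and Ccl24, an eosinophil chemokine, at 4.99 and 5.16 against 409, so free RNA was not excluded there. Ccl24 was higher in the 6 classes where it was measured (4.07). The immunoglobulin genes Igha (2.19) and Jchain (1.64) were higher in all 7, beside a plasma cell share 2.58 times as large. Saa3 was lower in all 7 (-1.61) and haptoglobin, Hp, by 1 or more in 6 (-1.74).

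Cdk8 (median 1.60) and the noncoding RNA Gm19951 (1.49) were higher in all 7 classes. They lie on chromosomes 5 and 12, and the level of Gm19951 over that of Cdk8 stayed between 0.592 and 1.20 in every class of both libraries. The noncoding RNA Gm48099 (1.79, chromosome 14) and Cmss1 (1.28, chromosome 16) were also higher in all 7. The level of Gm48099 over that of Cdk8 stayed between 0.0327 and 0.0750. Whether these genes share reads or differ by library handling was not tested. Ccnjl, a cyclin-like gene, was lower in the 6 classes where it was measured (-3.69) and Taf10, a subunit of the general transcription factor TFIID, by 1 or more in 6 of 7 (-1.19).

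Few alveolar macrophages were retained from the library labelled KL_Gpx4. The tables argue against the cell filter on genes and mitochondrial UMIs, since without that filter the share ratio was 0.113 (0.0821 to 0.153). Doublet calls were still removed there, which left 10674 and 7520 cells. The share was lower in both the Xist and Y-linked fractions, with a larger ratio of 0.0595 (0.0281 to 0.112), which argues against animals of one sex. These fractions held 1 and 10 such cells of the library labelled KL_Gpx4. Neither kind of UMI was seen in 79.25% of the class there, against 53.55% in the library labelled KL, so both ratios are biased low. Cluster boundaries change the size, with a ratio of 0.35 (0.29 to 0.42) when the libraries were clustered separately, but not the whole of it, since over all retained cells, with no clusters used, the markers of the class had a median fold of 0.248 (0.238 to 0.272). A real loss of these cells stays open as a hypothesis, beside untested differences between animals, in cell recovery and in barcodes under 500 UMIs, which the tables lack.

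Gpx4 was higher together with its neighbours on chromosome 10. An extra dose of every gene in the stretch is argued against by the 3 of 12 measured genes that stood under 0.3 on the log2 scale. Animals of one sex do not account for it, since the median of the raised genes was 0.911 in one fraction of cells and 1.07 in the other. A variant linked to the Gpx4 locus cannot be told apart from other causes. Among 8865 windows of 10 genes across the genome the window of rank 1 holds Gpx4 (median 0.903, highest without it 0.592), but this was looked at after the neighbours were seen and restates the pattern, and the reads that would show the allele were not used.

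The type I interferon list was lower across classes. A few cells with a strong response in the library labelled KL are argued against, since without the top 5% of cells 7 of 7 classes stayed at -0.2 or below (-0.59 to -0.41), though in neutrophils the median of all genes lay as low. Animals of one sex in the pool do not account for it in 6 of 7 classes, which stayed there in both fractions, while neutrophils did not (0.00 and -0.07). With each cell thinned to 1000 UMIs, 6 of 7 classes stayed at -0.2 or below, with neutrophils at -0.18. Thinning gives each cell the same weight, so a heavier weight of deep cells does not account for those 6. It leaves each cell's share of UMIs per gene unchanged on average, so it cannot otherwise decide on a difference in UMI depth. The genotype and other differences between the animals of the 2 libraries stay open and were not tested. Free RNA and doublets left in the library labelled KL stay open as well. Lyz2, which can come from either, was lower in T and B cells of the other library.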
